A study of Haloferax volcanii with 9 samples.

How the data were processed

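Gene expression was measured by RNA sequencing in 9 libraries of Haloferax volcanii, a halophilic archaeon. There were 3 groups of 3 libraries each: the parental strain grown with iron, a troR knockout strain grown with iron, and the parental strain grown without added iron in medium treated with the iron chelator BPS. Strain H26, the parental strain, lacks pyrE; strain HV175 lacks both pyrE and troR. Per the labels' protocols, cultures moved from rich medium to minimal medium with iron, and after stationary phase to fresh minimal medium with or without iron, where they grew to mid-log phase at an OD600 of about 0.4. The iron concentration is 100 micromolar in the treatment protocol and 100 millimolar in the condition label, and both write the salt as Fe2SO4. The labels also differ on the library kit: the series design names a stranded KAPA kit and the extract protocol names KAPA Hyper Prep. Ribosomal RNA was depleted with RiboZero, and all libraries ran pooled in 1 lane, per the labels' protocols.

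The deposited files hold raw read counts per gene, 1 file per library, with no normalization. Per the submitters' processing notes, FastQC, Trim Galore, cutadapt, Bowtie2, SAMtools, HTSeq and DESeq2 were used; their versions, the genome build, the annotation and the strand setting of the counting are not given in the sources used here. Without the strand setting, reads of a gene and of an antisense partner cannot be told apart. Each file has 3909 gene entries and 5 entries of reads that were not assigned to a gene. The unassigned entries stayed out of library sizes and tests. Between 38.5% and 77.7% of all reads fell in genes; reads of low mapping quality were 11.7% to 47.1%, reads outside any gene 5.50% to 12.5%, ambiguous reads 0.411% to 2.42% and reads that did not align 0.486% to 5.99%. Gene reads ranged from 6240558 to 25281398 per library. The smallest library was replicate 2 of the parental strain without iron, so its low counts are the least precise.

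Gene entries carry newer locus tags (HVO_RS numbers) or symbols. They were matched to a reference table of assembly ASM2568v1, used only for names and for which genes neighbour each other: 3603 entries matched by locus tag, 267 by symbol and 39 did not match. Genes are written here with their symbol or their older HVO tag. Of the entries, 24 pool several loci that share a symbol, among them coxB, trxA, pstA and pstC. Values of near-identical copies, overlapping genes and antisense pairs are uncertain, since the handling of shared reads is not given.

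Counts were tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) with TMM factors, filterByExpr, robust estimation and 1 coefficient per group over all 9 libraries. The filter removed 167 entries and 3742 were tested. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05, and the standard error (SE) of a log2 fold change is its absolute value divided by the square root of F. Contrasts were knockout against parental strain with iron, parental strain without against with iron, and knockout with iron against parental strain without iron. Levels are CPM computed by edgeR from the TMM-scaled library sizes, with SD over the 3 libraries of a group. The fitted biological coefficient of variation was 0.560. Per the labels the libraries of a group came from triplicate cultures, and p-values measure the spread between these samples.

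The gene lists were tested with camera of limma 3.58.1 on voom values at a preset correlation of 0.01, two-sided, adjusted over the 14 lists with 3 or more members. Camera with an estimated correlation and fry were run beside it. The 21 lists were defined as patterns of product words and symbols before the data were examined. The reference table holds no product text, so members were found by symbol alone: 4 lists had no member (siderophore synthesis, iron-sulfur proteins and ferredoxins, ATP synthase, DtxR family and metal regulators) and 3 had 1 or 2 members, which are described and not tested. Most genes of the organism carry no symbol in the table, so each list is a small part of its pathway. The chaperone list also took in panB by its symbol pattern, and the iron uptake list held only btuC, taken in likewise.

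The genes named in the text follow a rule fixed before the data were examined: troR and pyrE, up to 10 genes with the largest rise and 10 with the largest fall among genes that passed the test with a mean log2 CPM of at least 3 and no overlap between the groups' libraries, and up to 4 members of each list with the smallest p. For the contrast of knockout with iron and parental strain without iron the number was 5 in each direction. The count of the ribosomal protein list adjusted over the list alone is not reported here. Genes named outside the rule are said to have been chosen after their values were seen.

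The fits were tested on simulated counts for the knockout comparison with 50 genes each changed 2-, 4-, 8- and 16-fold. At the fitted spread, 2%, 14%, 68% and 88% of these genes were recovered among 3721 genes tested, with 4 false calls. At a much smaller spread, 84%, 98%, 100% and 100% were recovered among 3733 genes, with 7 false calls. A list of moved genes reached an adjusted p of 3.37e-25 by camera and 0 of 20 lists of unmoved genes were called. Genes were drawn independently in these counts, so they cannot show how camera behaves for lists whose genes move together. In the data the estimated correlation was 0.246 for branched-chain amino acid synthesis in the knockout comparison. It was 0.601 for cobalamin synthesis in the iron comparison.

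Alternatives planned before the data were examined were RLE size factors, library totals only, DESeq2 1.42.0, no filter on low counts, a mean count of at least 50, only the 2 groups compared, the replicate number as a block, a 2-fold minimum, an adjusted p under 0.01, no rRNA or tRNA entries, and leaving out each library in turn. Chosen after seeing the data were leaving out 2 libraries that stand apart from their groups, voom with sample quality weights, leaving out csg, rnpB and ffs, fits of 2 groups less 1 library, the naming rule applied without 1 library, and the lists of symbol stems and of the siderophore region. Figures were drawn with matplotlib 3.10.9. No coordinates are given because the build is not named.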

Results

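The transcriptome of Haloferax volcanii was profiled in 9 libraries from 3 groups of triplicate cultures. The parental strain and a strain lacking troR, the gene of a transcription factor, were grown in minimal medium with iron, and the parental strain also without iron. The series asks whether TroR takes part in iron homeostasis. Gene reads were 19139239, 20258375 and 25092731 in replicates 1 to 3 of the parental strain with iron, 25281398, 19808703 and 16324194 in the knockout, and 15584793, 6240558 and 16347953 in the parental strain without iron. The S-layer glycoprotein gene csg took the largest share of gene reads in every library, from 12.7% to 53.2%.

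Libraries within the knockout group were close to one another (Pearson r of log2 counts across genes 0.992 to 0.996), and so were replicates 2 and 3 of the parental strain with iron (r = 0.997). Replicate 1 of the parental strain with iron stood apart from them, with r = 0.713 and 0.716. Its csg share was 12.7% against 50.0% and 53.2%. Its share of tuf, encoding the translation elongation factor, was 1.94% against 0.178% and 0.188%. For 4 named ribosomal protein genes the share was 1.44% against 0.068% and 0.071%. High tuf and ribosomal protein shares were not particular to that library. In replicates 1 to 3 without iron tuf took 1.25%, 0.204% and 1.16%, and the ribosomal protein genes 0.62%, 0.028% and 0.508%. Their csg shares were 26.7%, 13.9% and 17.2%. In the knockout csg took 37.5% to 42.5%, tuf 0.244% to 0.307% and the ribosomal protein genes 0.092% to 0.127%. Without iron, replicates 1 and 3 had r = 0.955, and replicate 2 had r = 0.826 and 0.787 with them. These correlations are across genes, which are not independent replicates. None of the 9 pairs of libraries within a group agreed within sampling noise, with chi-square per degree of freedom from 35.4 to 4818, so none was counted as 1 library. In the principal component analysis, replicate 1 of the parental strain with iron lay with the libraries without iron on the component that held 50.0% of the variance.

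**Figure D1:**
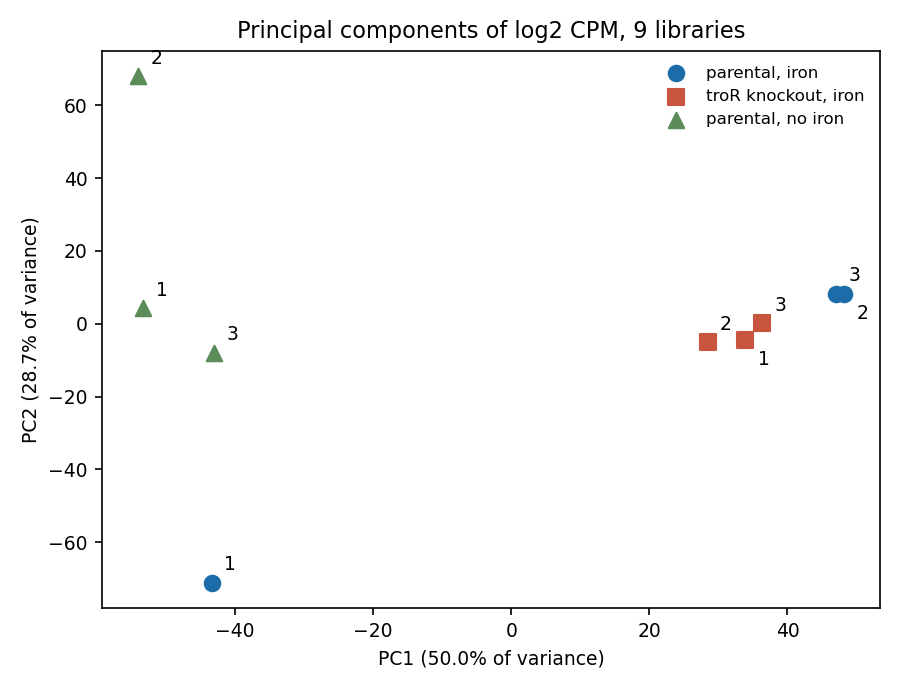
Principal components of log2 CPM; the horizontal axis holds 50.0% and the vertical axis 28.7% of the variance, each point is a library and the digit is its replicate number. Replicate 1 of the parental strain with iron lies far from replicates 2 and 3, and replicate 2 without iron lies far from replicates 1 and 3 on the vertical axis.

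The targeted gene, troR (HVO_RS08835, older tag HVO_0863), matched the labels in each library. It had 4871, 1727 and 2184 reads in the parental strain with iron, 1739, 1004 and 2814 without iron, and 11, 1 and 14 in the knockout. In CPM this was 144 ± 2.21 (SD, n = 3), 118 ± 27.8 (SD, n = 3) and 0.507 ± 0.485 (SD, n = 3). Genes on both sides were counted in the knockout: HVO_0862 had 2314, 1941 and 1475 reads there, and HVO_0864 had 61, 50 and 33. The iron-sulfur cluster assembly genes sufB and sufD lie 3 and 2 genes from troR in the reference and had CPM of 1219 to 1259 and 1045 to 1061 in the knockout. Their log2 fold changes in the knockout were -0.58 ± 0.38 (SE) and -0.58 ± 0.39 (SE), with edgeR adjusted p of 0.617 and 0.634. The pyrE locus (HVO_0333), deleted in both strains, had 3 to 21 reads per library.

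In the knockout with iron, troR and queC fell against the parental strain with iron. queC (HVO_1716) encodes an enzyme of 7-deazaguanine synthesis, on the route to a modified base of tRNA, and went from 192 ± 124 CPM (SD, n = 3) to 5.63 ± 0.367 (SD, n = 3), a log2 fold change of -5.09 ± 0.60 (SE), below in 3 of 3 libraries. The adjusted p by edgeR was 0.0370 for queC and 0.0295 for troR, whose log2 fold change was -8.18 ± 0.86 (SE). HVO_1717 and HVO_1718, with the next locus numbers after queC and chosen after their values were seen, had log2 fold changes of -5.19 ± 0.77 and -4.81 ± 0.69 (SE) and an adjusted p of 0.0991 each. They were below in 3 of 3 libraries.

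No gene was called higher in the knockout by edgeR among 3742 genes. At an unadjusted p under 0.05, 111 genes lay higher and 222 lower, DESeq2 called 25 higher and 26 lower, and 25.1% of genes had no overlap between the groups against 10% by chance. The count depends on the libraries used: without replicate 1 of the parental strain with iron 34 genes were higher and 38 lower, without replicate 2 of it 0 and 4, without replicate 2 of the knockout 0 and 1, without replicate 2 without iron 0 and 3, and without knockout replicate 1 or 3, or replicate 1 or 3 without iron, 0 and 0. queC and troR were called in 13 and 14 of 21 other fits, and the fit of only the 2 groups called neither (adjusted p = 0.179 for both). The 10% by chance, here and below, is an expectation per gene. Genes move together, so the share in a single split can lie far from it, and its spread over splits was not computed.

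The siderophore region, a run of 6 genes from HVO_B0041 to HVO_B0046 known for siderophore synthesis, was not found by the fixed lists and was added after the data were seen. Its 6 genes were higher in 3 of 3 knockout libraries, with log2 fold changes of 3.39 to 3.71, SE of 1.56 to 1.68 and edgeR adjusted p of 0.555 to 0.558. HVO_B0046 had 1881 ± 320 CPM (SD, n = 3) in the knockout and 29.9, 253 and 239 CPM in the parental strain with iron. HVO_B0041 had 271 ± 156 CPM (SD, n = 3) against 25.8 ± 6.95 (SD, n = 3). As a list the region was higher by camera (p = 2.61e-05), with p = 0.122 with an estimated correlation. The 6 genes passed in 2 of 21 other fits, both chosen after seeing the data: the 2 groups without replicate 1 of the parental strain (adjusted p 1.15e-06 to 0.0144) and voom with quality weights (0.00228 to 0.00425).

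The ferritin-like gene dpsA (HVO_0536), the only member found of the iron storage list, had 1166, 994 and 1363 CPM in the knockout and 710, 9716 and 9536 in the parental strain with iron. Its log2 fold change was -2.50 ± 1.11 (SE) with an adjusted p of 0.555. HVO_0538, chosen after its values were seen, had 333 ± 75.2 CPM (SD, n = 3) in the knockout and 21.1 ± 14.2 (SD, n = 3) in the parental strain, with a log2 fold change of 3.98 ± 1.41 (SE) and an adjusted p of 0.555. dpsA and HVO_0538 were each called in 3 of 21 other fits. Among these was the fit of the 2 groups less replicate 1 of the parental strain, chosen after seeing the data (edgeR adjusted p 8.71e-07 and 1.67e-05).

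Genes of tryptophan synthesis were higher in the knockout without reaching the threshold in the fit of all libraries. trpE, trpF, trpD and trpG had log2 fold changes of 2.57, 2.48, 2.17 and 2.03 with adjusted p of 0.412 to 0.555. Without replicate 1 of the parental strain with iron these were 3.18, 3.17, 3.18 and 2.92, and all 4 rose by edgeR (adjusted p 0.0358 to 0.0421). In that fit, run by the naming rule after the data were seen, HVO_2128, HVO_0032 and HVO_2844 also rose, by 2.73, 2.04 and 1.90. HVO_2447A, HVO_2448 and the glyceraldehyde-3-phosphate dehydrogenase gene gap fell, at -2.65, -2.62 and -2.07, as did HVO_1717 and HVO_1718, at -5.57 and -5.19.

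Among the fixed lists, branched-chain amino acid synthesis was higher in the knockout. Its 9 genes had a median log2 fold change of 1.75 and an adjusted p of 0.0104 by camera, and 0 of 9 passed singly, also when adjusted over the list alone. The adjusted p was 0.806 with an estimated correlation, and 0.193 without replicate 1 of the parental strain with iron. ilvD was 1259 ± 223 CPM (SD, n = 3) against 375 ± 237 (SD, n = 3), and leuB, leuC and leuD had log2 fold changes of 1.92, 1.77 and 1.94, each above in 3 of 3 libraries with an adjusted p of 0.555 to 0.562.

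The other 13 lists tested were not called in the knockout by camera. The adjusted p was 0.277 for oxidative stress response and thiamine synthesis, 0.348 for ribosomal proteins and motility, 0.359 for chaperones, 0.489 for metal transport, 0.498 for iron-sulfur cluster assembly, 0.540 for denitrification, 0.625 for the citric acid cycle, cobalamin and heme synthesis, 0.650 for phosphate uptake and 0.657 for the respiratory chain. In these 13 lists 0 members passed over all genes tested, and outside the ribosomal protein list 0 passed when adjusted over the list alone. The chaperonin gene thsA (HVO_0778) had a log2 fold change of -5.58 ± 1.73 (SE) that rested on replicate 1 of the parental strain, at 6240 CPM against 76.0 and 72.7 in replicates 2 and 3. The transporter gene btuC (-0.53) and the transposase genes tnpA (-0.55 and -0.98) did not pass.

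**Figure D2:**
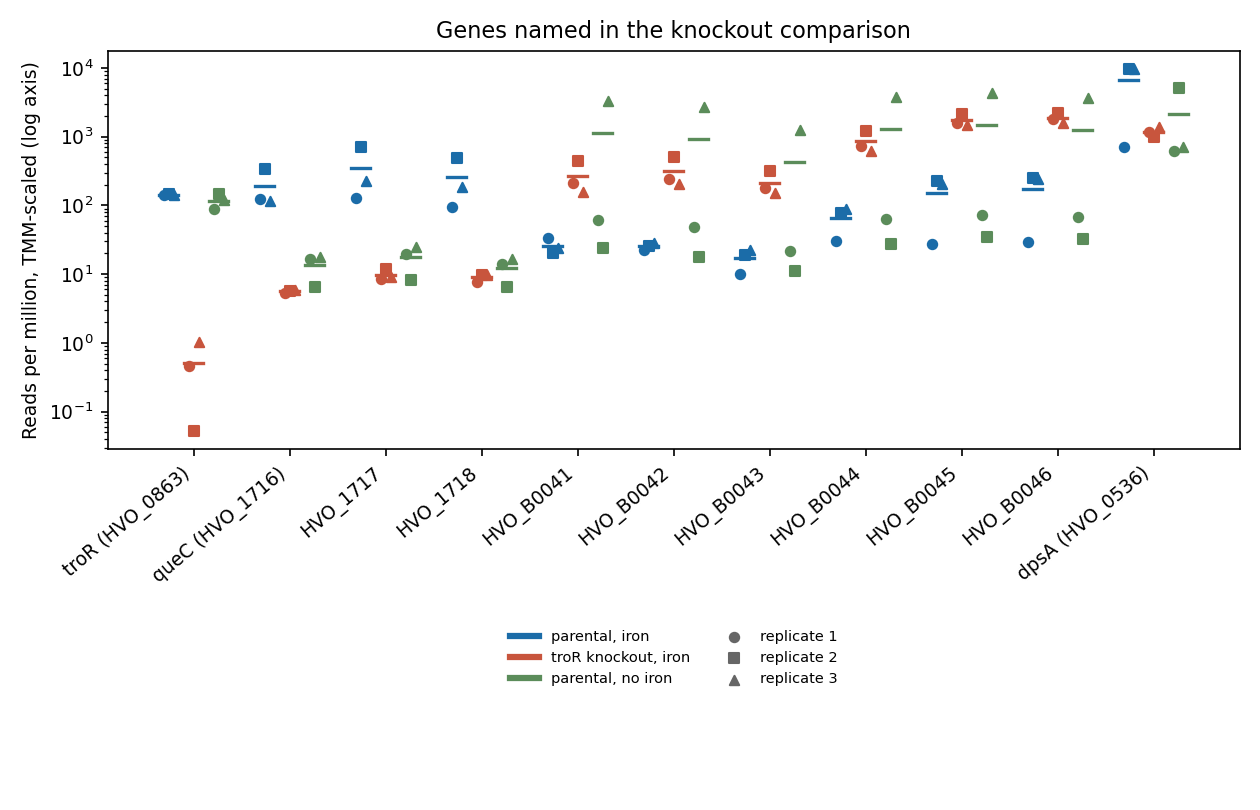
CPM per library on a log axis for troR, queC, HVO_1717, HVO_1718, the 6 genes of the siderophore region and dpsA; symbols give the replicate, colours the group and lines the mean of 3 libraries. The siderophore region was at 150 to 2224 CPM in the knockout, and without iron it was at 1245 to 4348 CPM in replicate 3 and 11.0 to 71.7 CPM in replicates 1 and 2.

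Without iron, the parental strain had many genes at other levels than with iron. Genes that rose included HVO_0204, from 40.99 ± 5.45 to 1557 ± 899 CPM (SD, n = 3 each), a log2 fold change of 5.25 ± 0.60 (SE), and 3 genes with nearby locus numbers, HVO_0531, HVO_0532 and HVO_0534, at 3.02 ± 0.46, 3.77 ± 0.48 and 3.91 ± 0.46 (SE). HVO_2118 and HVO_2119 rose by 2.96 ± 0.27 and 4.13 ± 0.39. The genes paaA, paaB, paaC, paaD and paaE, named for phenylacetate breakdown, rose by 2.81 to 3.59. Each of these genes was above in 3 of 3 libraries, with an edgeR adjusted p of 0.00266 to 0.0341. They were chosen after their values were seen, and all but paaB and paaE were called in 19 or 20 of 21 or 22 other fits. paaB was called in 11 of 21 other fits and in 1 of 9 less 1 library, and paaE in 15 of 21. Levels of paaA to paaE were low. Mean CPM was 0.264 (paaE) to 2.02 (paaA) with iron, and 2.05 (paaE) to 17.3 (paaC) without. Each of them was highest in replicate 2 without iron.

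Genes that fell without iron included sod (HVO_A0475), encoding superoxide dismutase, which went from 274 ± 175 to 23.2 ± 2.57 CPM (SD, n = 3 each), a log2 fold change of -3.56 ± 0.62 (SE, adjusted p = 0.0136). By the naming rule HVO_A0039, HVO_2674 and HVO_0544 fell, with log2 fold changes of -5.66, -5.01 and -4.48, SE of 0.70, 0.59 and 0.46 and edgeR adjusted p of 0.00587, 0.00587 and 0.00374. HVO_A0171, HVO_2657, HVO_2098, HVO_A0012 and HVO_A0601 fell, at -4.48, -4.44, -4.44, -4.23 and -4.05. HVO_1717 and HVO_1718 fell, at -4.34 and -4.37, and queC fell by 3.81 (adjusted p = 0.00969). Chosen after their values were seen, HVO_1981 went from 1124 ± 195 to 71.5 ± 29.6 CPM (SD, n = 3 each), and HVO_2654, HVO_2655 and HVO_2656 fell, at -3.14, -3.18 and -3.10. HVO_2098, HVO_2657, HVO_A0601 and HVO_A0012 lost their call in 8, 7, 6 and 4 of 9 fits less 1 library. HVO_A0601 (HVO_RS04545) was at 132 CPM in replicate 1 with iron and at 10.3 and 10.5 CPM in replicates 2 and 3, and without replicate 1 its log2 fold change was -1.75.

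The 10 largest rises by the naming rule were HVO_A0295A, HVO_A0300, HVO_A0301, HVO_A0295, HVO_A0306, HVO_A0297, HVO_A0304, HVO_A0305, HVO_B0303 and HVO_1984A, with log2 fold changes of 7.26 to 10.69. They were above in 3 of 3 libraries with edgeR adjusted p of 0.0162 to 0.0483, but their size came from replicate 2 without iron. HVO_A0301 was at 7957 CPM there and at 40.8 and 25.1 CPM in replicates 1 and 3, against 2.69 ± 1.58 (SD, n = 3) with iron. Without replicate 2 the log2 fold change of HVO_A0301 (HVO_RS03200) was 3.63 and its adjusted p 0.0405; HVO_A0304 (HVO_RS03215), HVO_B0303 (HVO_RS01465) and HVO_1984A (HVO_RS14225) were also still called, at log2 fold changes of 1.83, 3.79 and 4.84, and the other 6 were not (adjusted p 0.0708 to 0.114). The naming rule applied without replicate 2, after the data were seen, put HVO_0204, HVO_0534, HVO_0490, HVO_0532, HVO_2670 and HVO_A0576 among the rises at 3.83 to 4.78, and HVO_A0170, HVO_A0173, HVO_A0177 and HVO_A0175 among the falls at -7.37 to -5.76. HVO_B0041 and HVO_B0042 of the siderophore region rose by 6.02 and 5.76 in that fit, by their level in replicate 3.

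In all, 279 genes rose and 222 fell without iron by edgeR, of which 277 and 216 by at least 2-fold, and 27.5% of genes had no overlap between the groups against 10% by chance. With library totals in place of TMM factors, the calls were 163 higher and 34 lower, 82.7% higher against 55.7%, and the median log2 fold change of all genes moved from -0.14 to 0.23; the folds above are relative to the TMM scale. A fit of only the 2 groups called 0 genes (766 at an unadjusted p under 0.05), the same fit less replicate 1 with iron, chosen after seeing the data, called 984, and DESeq2 called 921 with all libraries. Leaving out replicate 1, 2 or 3 of the parental strain with iron gave 1820, 109 or 79 genes, knockout replicate 1, 2 or 3 gave 169, 176 or 188, and replicate 1 without iron gave 239.

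Among the fixed lists, cobalamin synthesis was higher without iron. Its 10 genes had a median log2 fold change of 1.53 and an adjusted p of 0.00748 by camera, with 0.945 with an estimated correlation, and 0 of 10 passed singly, also when adjusted over the list alone. cobN had 1882, 763 and 1462 CPM without iron, 33.2 and 33.3 CPM in replicates 2 and 3 of the parental strain with iron, and 938 CPM in replicate 1, the library that stood apart. The list was not called with library totals (adjusted p = 0.0743).

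In the oxidative stress list 1 of 6 genes fell over all genes tested, sod (HVO_A0475), and 2 of 6 adjusted over the list alone. The list holds another entry named sod, which did not pass either way. The added member was the catalase-peroxidase gene katG, at -2.22 ± 0.63 (SE, adjusted p = 0.0507). The list had an adjusted p of 0.0524 by camera and 0.967 with an estimated correlation. Of 6 heme synthesis genes hemB, encoding porphobilinogen synthase, fell by 1.26 ± 0.30 (adjusted p = 0.0328, camera adjusted p 0.946 for the list). Of 4 respiratory chain genes nuoK rose by 1.09 ± 0.28 (adjusted p = 0.0371, list 0.946). The transporter gene btuC, the only member found of the iron uptake list, fell from 35.4 ± 11.4 to 13.9 ± 0.849 CPM (SD, n = 3 each), a log2 fold change of -1.35 ± 0.30 (SE, adjusted p = 0.0274). It entered that list by its symbol alone and what it transports was not checked, so its fall is not a result for iron uptake. btuC, hemB and nuoK were called in 11, 11 and 10 of 22 other fits. dpsA had a log2 fold change of -1.62 ± 1.08 (SE, adjusted p = 0.340).

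The chaperone and proteolysis list of 14 genes had 0 members past the threshold, a camera adjusted p of 0.0524 and a fry adjusted p of 0.0117, with a median log2 fold change of -0.90. Of 4 iron-sulfur cluster assembly genes 0 passed; their fry adjusted p was 0.0109 and their camera adjusted p 0.225, with sufU at -1.48 ± 0.57 (SE) and sufB at -0.67 ± 0.38 (SE). Both lists had an adjusted p of 0.765 with an estimated correlation. Fry asks whether a list moves on balance and does not compare it with other genes. Camera adjusted p was 0.444 for metal transport, 0.793 for denitrification and ribosomal proteins, 0.826 for the citric acid cycle, and 0.946 for branched-chain, phosphate, motility and thiamine genes. In these 8 lists 0 members passed over all genes, and outside the ribosomal protein list 0 passed when adjusted over the list alone. The transposase genes tnpA were at 0.39 and -0.23 and did not pass.

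**Figure D3:**
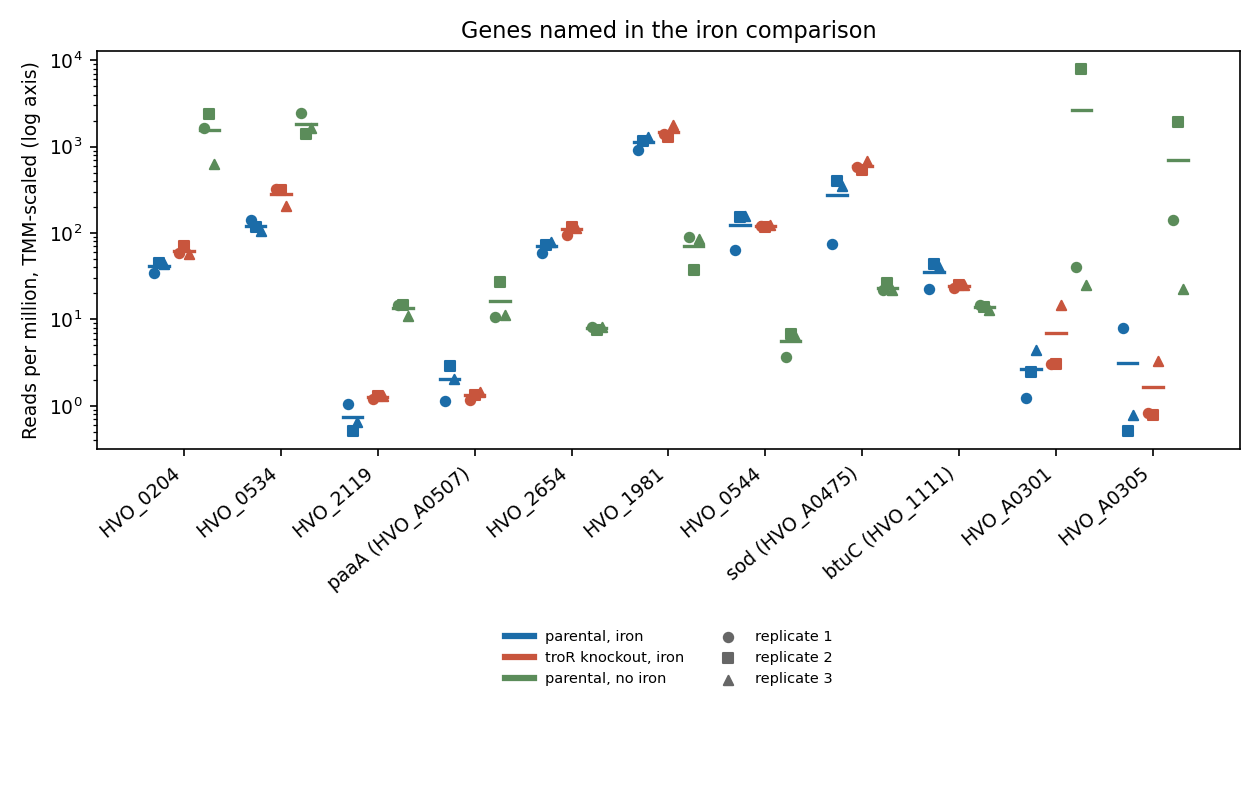
CPM per library on a log axis for 11 genes of the iron comparison; symbols give the replicate, colours the group and lines the mean of 3 libraries. HVO_0204, HVO_0534, HVO_2119 and paaA lie higher in all 3 libraries without iron, sod, btuC, HVO_0544, HVO_1981 and HVO_2654 lie lower in all 3, and HVO_A0301 and HVO_A0305 reach their highest level in replicate 2 without iron.

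The knockout with iron and the parental strain without iron differed directly in 351 genes. By edgeR 124 were higher in the knockout and 227 lower, 54.0% of genes had no overlap between the groups against 10% by chance, and troR was lower by a log2 fold change of -7.89 ± 0.85 (SE, adjusted p = 0.00413). HVO_A0171, HVO_2657, HVO_A0039, HVO_A0177 and HVO_A0549 were higher in the knockout, at 5.47, 4.94, 4.91, 4.81 and 4.74; the call was lost in 1, 5, 0, 5 and 0 of 9 fits less 1 library. HVO_A0305, HVO_A0579, HVO_A0578 and HVO_B0303 were lower, at -8.75, -6.87, -6.63 and -6.61, and each had its highest level in replicate 2 without iron. Without that library they were at -5.66, -4.35, -3.94 and -2.69, and the call was lost in 5, 3, 3 and 5 of 9 fits less 1 library. The sod gene HVO_A0475 was higher in the knockout by 4.69 ± 0.65 and katG by 2.56 ± 0.64 (SE, edgeR adjusted p 0.00721 and 0.0432).

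Of the fixed lists 2 were called in this contrast. The oxidative stress list was higher in the knockout (camera adjusted p = 0.00923, and adjusted p = 0.682 with an estimated correlation), with 2 of 6 genes past the threshold and 3 when adjusted over the list alone. Cobalamin synthesis was lower (adjusted p = 0.00507, and adjusted p = 0.682 with an estimated correlation), with 1 of 10 genes past the threshold, cobN, and 9 when adjusted over the list alone. hemB was higher by 1.26 ± 0.30, and nirK, encoding nitrite reductase, and sucD, encoding a succinyl-CoA synthetase subunit, were lower, at -1.29 ± 0.29 and -2.24 ± 0.54 (SE, adjusted p 0.0392, 0.0287 and 0.0389). With library totals 136 genes were called, DESeq2 called 885, and a fit of only these 2 groups called 1244. Without replicate 1 of the parental strain with iron 1638 genes were called, without knockout replicate 1, 2 or 3 there were 18, 34 or 38, and without replicate 1 without iron 138.

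The overlap of the comparisons asks whether loss of troR with iron moves the genes that iron limitation moves. queC was the 1 gene that fell in both, and 0 genes rose in both, by edgeR. Simulated counts in which no gene differed between the groups, with simulated control libraries, gave 0. With no gene changed few calls arise in either comparison, so that 0 was close to fixed in advance. It does not measure what shared controls add to the overlap. Independent lists would share 0 higher and 0.119 lower. Across genes the log2 fold changes had Pearson r = 0.190, against a mean of 0.496 (0.462 to 0.521) in 20 simulations with shared controls, and a covariance of 0.259 against 0.231. Without replicate 1 of the parental strain with iron, 28 genes rose and 33 fell in both, against 8.71 and 8.72 for independent lists. The simulated count was again 0, with the same limit. r was then 0.497 against 0.607 simulated, and the covariance 0.702 against 0.188. trpE, trpF and trpG rose in both comparisons in that fit. The 3 control libraries cannot be split into parts of 2, and part of any excess may come from the shared controls. The simulations gave all groups the same spread per gene, but in the data the spread was uneven. Over 3027 genes the SD of the log2 ratio of replicate 1 with iron to replicates 2 and 3 was 2.10. Between replicates 2 and 3 it was 0.222. The simulated r and covariance can therefore lie far from what the shared controls add in these data, with or without replicate 1.

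The main chromosome held 95.2% ± 2.90, 95.05% ± 0.327 and 91.2% ± 2.26 of gene reads (SD, n = 3 each) in the parental strain with iron, the knockout and the parental strain without iron. The plasmid pHV4 held 2.19% ± 1.02, 2.18% ± 0.029 and 3.69% ± 2.15, and pHV3 held 1.85% ± 1.38, 2.16% ± 0.278 and 4.23% ± 2.58. No two-sided exact permutation test of a replicon share, with or without csg, rnpB and ffs, gave p under 0.2, and the smallest p possible with 3 against 3 is 0.1.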

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

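The tests of single explanations in this part were chosen after the patterns were seen, and the counts of splits were planned before. The share of reads that did not align lies outside the gene counts and was noted because it was above the highest parental library with iron, at 1.00%, in each library without iron: 2.81%, 5.99% and 2.63% in replicates 1 to 3. The knockout libraries had 0.686% to 1.14%, and no explanation of this share was tested.

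Replicate 1 of the parental strain with iron stood apart from replicates 2 and 3 and decided most of the knockout comparison. A swap with replicate 2 without iron was tested with each library held out singly, where replicate 2 without iron lay nearer its own group for 72.4% of 479 genes and replicate 1 with iron nearer its own for 33.6% of 1818 genes; after the splits were seen, a test with both held out was added, where replicate 2 without iron lay nearer the libraries without iron for 63.1% of 2610 genes, as did replicate 1 with iron for 67.7%, which argues against a swap by a small margin, although exchanging these 2 labels gave 722 genes against 501 as labelled. A wrong iron label of replicate 1 alone, or a culture that differed, stays open. Over 862 genes chosen without it, replicate 1 lay nearer the libraries without iron for 66.2%. Libraries without iron, each held out together with it by the same rule, gave 67.6% to 93.9%. Their gene sets were other ones, 945 to 1381 genes with a gap to the remaining libraries only. The percentages are therefore not strictly comparable and cannot decide the label. HVO_0204, HVO_0534 and HVO_2654 lay at 34.7, 141 and 59.0 CPM in replicate 1, near replicates 2 and 3 with iron. These genes were picked from a fit that counts replicate 1 as with iron, so they cannot decide its label. A mixture with RNA of cultures without iron would need 1 share for all genes. The median share was 0.651 in 824 genes higher without iron and 0.993 in 629 lower. The difference was 0.342 (bootstrap 95% interval 0.249 to 0.429), with wide quartiles. The shares were taken against the mean of the 3 libraries without iron, which differ among themselves. Genes high in replicate 2 without iron alone raise that mean, so unlike shares cannot tell whether a mixture occurred. A few abundant genes setting the total would move other genes by 1 factor, but the SD of the log2 ratio to replicates 2 and 3 was 2.10 over 3027 genes, against 0.222 between replicates 2 and 3; growth state was not tested and may also differ.

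The siderophore region was high without iron in replicate 3 alone, at 72.5 to 84.7 times the mean of replicates 1 and 2. Reads of a knockout library in replicate 3 would leave the genes below the knockout level, but 6 of 6 lay above the highest knockout library, by 1.64 to 7.36 times, and a knockout culture in its place is argued against by troR at 118 CPM, against at most 1.02 in the knockout. With all 9 libraries 0 genes were called higher in the knockout, so other genes were taken from the fit of the 2 groups less replicate 1 with iron, where 238 genes outside the region were called at least 2-fold higher. Of these 42.0% (100 of 238) were highest without iron in replicate 3, against a median of 28.6% in 10000 random sets of like level; a state partly shared with the knockout may be present, as a hypothesis that rests on that fit. The design gives no label that sets replicate 3 apart, and no biological explanation was tested.

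HVO_A0292 to HVO_A0307 on plasmid pHV4 were high without iron in replicate 2 alone, with 17 of 17 genes above every other library and a median log2 ratio of 7.95 to replicates 1 and 3. Reads carried over from another library are argued against by the highest level elsewhere, 0.937% of that in replicate 2. Low depth is argued against by the lowest gene count of 253 reads in the region. A change of the whole plasmid is argued against by the median log2 ratio of 0.388 over 462 other pHV4 genes (quartiles -0.417 to 1.16). A local change of copy number or of transcription in that culture stays open as a hypothesis, since counts of RNA cannot separate them and no biological explanation was tested.

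For the knockout comparison, the 10 splits of the 6 libraries are too few for a share under 0.05; the real split called 2 genes and the highest other called 0 (1 split as large, the real one). For the iron comparison they are also too few; the real split called 501 genes and the highest other 722 (2 splits as large). That other split is the exchange of replicate 1 with iron and replicate 2 without iron, which points to a structure of these samples and goes with a swap, unlike the test with both libraries held out. For the knockout against the parental strain without iron the 10 splits are too few, with 351 genes and 0 in the highest other (1 split as large). For lists, again too few, the real split called 1 in each comparison and the highest other 6 with the knockout and 7 with iron (7 splits as large in both). Over 60 drawn splits of the 9 libraries, 2 gave as many genes called in both comparisons in one direction, the real one with 1 gene and another with 271. That share is under 0.05, but it rests on 1 gene.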

How the results depend on the processing

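Leaving out both libraries that stand apart, voom with quality weights, leaving out csg, rnpB and ffs, and fits of 2 groups less 1 library were chosen after seeing the data; the other alternatives were planned. There were 1553 values of named genes under the alternatives, with the 2-fold minimum and the adjusted p under 0.01 left out. Of these 1173 kept their direction and side of the threshold, 315 lost and 65 gained a call, and 0 reversed. Gene lists were not in this count. Many of the genes were named for large changes without overlap between the groups, or after their values were seen. Few reversals could therefore arise. In what follows the counts are given as higher and lower in the knockout, higher and lower without iron, different between knockout and no iron, and genes called in both comparisons in one direction; for changes below the cause was not tested unless the setting itself names it. As reported they were 0, 2, 279, 222, 351 and 1, with r = 0.190 between the comparisons. Library totals gave 0, 0, 163, 34, 136 and 0, with r = 0.295. DESeq2 gave 25, 26, 443, 478, 885 and 32. Fits of only the 2 groups gave 0, 0, 0, 0, 1244 and 0, with 357 and 766 genes at an unadjusted p under 0.05. An adjusted p under 0.01 gave 0, 0, 38, 29, 65 and 0 by its stricter threshold. The replicate block gave 0, 0, 110, 56, 142 and 0, with 201 genes at an unadjusted p under 0.05 in the knockout comparison. Of 9 same-number pairs 3 had correlated deviations from their group means over 0.1 (range -0.339 to 0.318), and 7 of 18 other pairs did. Deviations within a group are tied to one another and follow a library that stands apart. This check therefore cannot tell whether the numbers pair the samples. Without both libraries that stand apart the counts were 588, 587, 1331, 1282, 2455 and 893, with r = 0.578. Voom with quality weights gave 975, 995, 1222, 1201, 2161 and 1226, with r = 0.525 and weights of 0.0280 for replicate 1 with iron and 0.107 for replicate 2 without. The 2 groups less replicate 1 with iron gave 934, 917, 500 and 484, and 565 in both, with r = 0.497. The 2 groups less replicate 2 without iron gave 0 and 0 for iron (655 genes at an unadjusted p under 0.05) and 2331 for the direct contrast. Leaving out each library in turn gave 0 to 34 higher and 0 to 38 lower in the knockout, 39 to 960 higher and 40 to 860 lower without iron, 18 to 1638 different between knockout and no iron, 0 to 61 in both, and r of 0.135 to 0.497. Of the 501 genes called for iron, 475 were also called by DESeq2, 147 with library totals, 166 with the replicate block and 0 with only the 2 groups; 493, 109 and 79 without replicates 1, 2 and 3 with iron, 168, 175 and 187 without knockout replicates 1, 2 and 3, 229, 362 and 288 without replicates 1, 2 and 3 without iron, and 498 without both libraries that stand apart. RLE factors, no filter, a mean count of 50, a 2-fold minimum, no rRNA or tRNA entries and no csg, rnpB and ffs kept the counts within 1.5 times. Depth limits low genes most in replicate 2 without iron, with 6240558 gene reads.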

Other observations

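The lists of symbol stems in this part, 51 per comparison, were tested only after the data were seen. Genes of tryptophan synthesis were the stem with the smallest adjusted p in the knockout, with 7 trp genes at a median log2 fold change of 2.03 and 0 of 7 past the threshold singly (camera adjusted p = 5.91e-09, and adjusted p = 0.967 with an estimated correlation). The stems leu and hut, for leucine synthesis and histidine breakdown, had medians of 1.85 and 1.24 (adjusted p 0.0265 and 0.0163, and 0.967 with an estimated correlation). Without iron, 6 of 6 paa genes rose, paaB in 11 and paaE in 15 of 21 other fits, with a median of 3.25 (adjusted p = 7.87e-05, and 0.715 with an estimated correlation), and 3 of 7 trp genes rose: trpE, trpG and trpF, at 3.24, 3.00 and 2.67 (list adjusted p 0.00292, and 0.850 with an estimated correlation). The calls of trpE, trpG and trpF without iron were lost in 2, 2 and 5 of 9 fits less 1 library. The his genes, for histidine synthesis, were lower, with 1 of 10 past the threshold and a median of -0.70 (adjusted p = 0.0249, and 0.715 with an estimated correlation). Against the knockout, the 7 cas genes, for CRISPR-associated proteins, were higher in the parental strain without iron by a median of 3.63 in log2, written -3.63 in the contrast, with 0 of 7 past the threshold (adjusted p = 0.0144, and 0.720 with an estimated correlation).

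The genes in what follows were chosen after their values were seen, and no test of neighbouring genes as a group was run. Without iron HVO_A0535, HVO_A0536, HVO_A0537 and HVO_A0538 rose by 3.12, 2.46, 1.69 and 1.74 (edgeR adjusted p 0.00374 to 0.0281). HVO_2653, next to HVO_2654, fell by 1.99 without iron (adjusted p = 0.00992) and had a log2 fold change of 1.23 ± 0.30 (SE) in the knockout (adjusted p = 0.427). Without replicate 1 of the parental strain with iron, its knockout change was 1.04 (edgeR adjusted p = 0.0464). HVO_0531, HVO_0532 and HVO_0534, which rose without iron, had log2 fold changes of 0.96, 1.32 and 1.20 in the knockout with iron, an adjusted p of 0.555 each, and were lower there than without iron by direct test (adjusted p 0.00972 to 0.0251).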
